A study of Mus musculus with 8 samples.

How the data were processed

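RNA sequencing was carried out on NIH3T3 cells, a mouse fibroblast line, in 8 libraries that the labels place in 4 groups of 2: WT and Zmynd11 knockout (KO) cells, each at 0 h without treatment and after 2 h with recombinant mouse interferon-beta (IFN-β) at 100 units/ml. Per the labels' protocols, RNA was extracted with TRIzol, libraries were built on an automated preparation station and fragments were sequenced in pairs. The source field names NIH3T3 while the extraction protocol speaks of embryonic fibroblasts, and the labels give no batch, date or clone.

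The authors deposited 1 table of raw counts per library, with 1 whole number of reads per gene symbol. Per the submitters' processing notes, bcl2fastq 2.15, STAR 2.5.2b, HTSeq and the mm9 build of the mouse genome were used; the role of each tool, the annotation and the strand setting are not given in the sources used here. Each table held 23304 gene symbols and 4 summary lines. The summary lines took 36.9 to 43.2% of all reads: 14.1 to 17.0% mapped to several places, 6.18 to 12.0% were unmapped, 12.8 to 17.3% lay in no gene and 0.489 to 0.553% in several genes. They were left out of library sizes and tests. Reads that map to several places were not assigned to genes, so near-identical families (guanylate-binding proteins, Irgm genes, Ifit and Oas genes, class I histocompatibility genes, ribosomal proteins) can be undercounted, and reads of overlapping or antisense genes cannot be told apart without strand.

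Gene reads summed to 13671013 to 21299120 per library. A single read was worth 0.0460 to 0.0700 CPM, where CPM stands for counts scaled to a common library size, and 3 reads, the limit that a count of 0 allows, 0.138 to 0.210 CPM. These limits cover counting error only. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups given, a minimum count of 10 and a minimum total of 15, which left 12807 genes. Libraries were scaled by TMM, and CPM use these scaled library sizes. A single quasi-likelihood model with 1 coefficient per group was fitted to the 8 libraries with robust dispersions. It has 4 residual degrees of freedom, and the biological coefficient of variation was 6.74%. Groups were taken from the labels, and no sample was regrouped by its values.

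There were 5 comparisons: 2 h against 0 h within WT and within KO, KO against WT at 0 h and at 2 h, and the interaction, the difference between the 2 h minus 0 h changes of KO and WT. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The genes to be named followed a rule: the 10 largest log2 fold changes in each direction among called genes with a mean of at least 1 CPM in a group and groups that do not overlap, Zmynd11, a preset group of interferon-induced genes in the IFN-β comparisons and the interaction, and up to 4 members of each gene list. Some genes that the rule names are not reported here. A fold against a group with no reads was computed against 3 reads summed over that group and is a lower bound.

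Of 29 gene lists, 26 had at least 3 tested members. Each was compared with the other genes by camera in limma 3.58.1 on voom values with an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated for each list. Called members were counted with p adjusted over all genes and with p adjusted over the list alone. The samples, tests, gene lists, naming rule and alternatives were fixed before the data were examined, except where a later choice is named. Alternatives were another composition factor (RLE), library size alone, DESeq2 1.42.0, no filter, a filter of 1 CPM in 2 libraries, fits of the 4 libraries compared, a replicate block, a test against a fold of 1.5, and leaving out each library. Where a group was left with 1 library, that library was assumed to vary like the others.

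Genes were assigned to chromosomes by symbol or by a unique synonym in a RefSeq table of the GRCm38.p6 assembly, which placed 12741 of the 12807 genes. That assembly differs from the build of the counts, so it served only for chromosome membership and gene order. The model was tested on simulated counts with 200 changed genes. These are far fewer than the 7837 and 7829 genes called between labelled 2 h and 0 h in WT and KO. Scaling and error rates in that setting were therefore not tested. For KO against WT at 0 h, simulated on 12555 genes, the model recovered 47 of 67 genes changed 1.5-fold, 54 of 67 changed 2-fold and 62 of 66 changed 4-fold, and it called 11 unchanged genes. For the interaction, simulated on 12560 genes, the numbers were 36 of 67, 50 of 67 and 58 of 66, with 10 unchanged genes called. In a separate simulation 1 whole chromosome was shifted and no other gene was changed. Removal of the shift took the calls over all 12598 genes from 593 to 0.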

Results

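Transcript levels were measured in NIH3T3 cells, an immortalised line of mouse embryonic fibroblasts, by RNA sequencing of 8 libraries. The labels describe unedited cells (WT) and cells in which Zmynd11 was knocked out by CRISPR (KO), each untreated (0 h) or given interferon-beta (IFN-β) at 100 units/ml for 2 h, with 2 libraries per group. Zmynd11 encodes a chromatin protein that reads a methylated form of histone H3.3, and IFN-β is a type I interferon that induces antiviral genes. Gene reads summed to 13671013 to 21299120 per library. Reads were found for 14847 to 15945 genes in 7 libraries and for 17498 genes in the library labelled KO 0 h replicate 2. The labels do not say that the libraries of a group came from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical.

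The targeted gene was examined first, as a check of the genotype labels. Zmynd11 stood at 122 ± 1.62 CPM in the libraries labelled WT 0 h and at 134 ± 4.26 CPM in those labelled KO 0 h (mean ± SD, n = 2 each). It stood at 3.40 ± 0.303 CPM in the libraries labelled WT 2 h and at 4.001 ± 0.978 CPM in those labelled KO 2 h. The libraries labelled 0 h held 1967 to 2511 reads of Zmynd11 each, and those labelled 2 h held 59 to 72. Zmynd11 was lower in libraries labelled 2 h than in those labelled 0 h among the WT labels (log2 fold change -5.16, SE 0.13, edgeR adjusted p = 1.27e-18) and among the KO labels (-5.11, SE 0.13, edgeR adjusted p = 2.24e-18). No difference between the KO and WT labels passed the test at 0 h (0.15, SE 0.09, edgeR adjusted p = 0.364) or at 2 h (0.19, SE 0.19, edgeR adjusted p = 1).

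The interferon-induced genes Ifit1 and Isg15 separated the libraries by labelled genotype instead, although not each such gene did, as given below for Gbp9. Ifit1, which encodes an antiviral protein that binds foreign RNA, stood at 1.30 ± 0.109 CPM in the libraries labelled WT 0 h, 2.84 ± 1.57 in WT 2 h, 213 ± 23.3 in KO 0 h and 388 ± 11.6 in KO 2 h. Isg15, a ubiquitin-like protein, stood at 4.80 ± 0.505, 3.56 ± 0.0742, 67.5 ± 4.28 and 72.5 ± 2.27 CPM in the same order. The level of Zmynd11 thus goes against the genotype label of the groups KO 0 h and WT 2 h. The reads were summed over the whole gene and the edited position is not given in the sources used here, so an allele that is transcribed but makes no protein would still yield reads. Such an allele could account for the reads of Zmynd11 in KO 0 h. It would not account for the low counts of 59 and 65 reads in WT 2 h, or of 72 and 67 in KO 2 h. Groups are named below only as they are labelled, and every direction is a direction between labels.

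**Figure D1:**
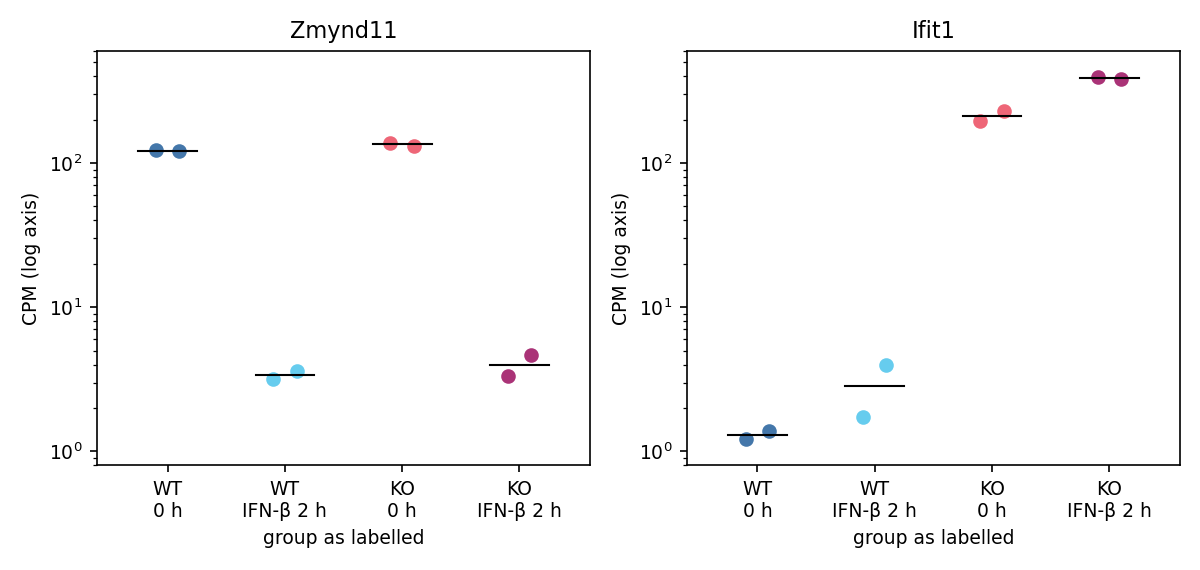
CPM of Zmynd11 (left) and Ifit1 (right) on log axes for each of the 8 libraries by labelled group, with points for libraries and lines for group means. Zmynd11 lies at 120 to 137 CPM in the 4 libraries labelled 0 h and at 3.18 to 4.69 CPM in the 4 labelled 2 h, whereas Ifit1 lies at 1.22 to 3.95 CPM in the 4 labelled WT and at 196 to 396 CPM in the 4 labelled KO.

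The first comparison asks which transcripts differ between 2 h and 0 h in cells labelled WT. By label it is the response to IFN-β, but Zmynd11 differed between these groups as well. In the libraries labelled WT 2 h, the tested genes of DNA replication, mitosis and cholesterol synthesis and 21 of 25 matrix genes were lower than in those labelled WT 0 h, while 11 of 19 immediate early genes and 12 of 14 interferon-inducible GTPases were higher. Of these 6 list calls, mitosis alone held with an estimated correlation (camera adjusted p = 0.038, and 0.0578 to 0.355 for the others). Col1a1, a chain of the main fibrillar collagen, fell from 10526 ± 362 to 928 ± 88.7 CPM (n = 2 each, log2 fold change -3.50, SE 0.09). Dlk1, a membrane protein of preadipocytes, fell from 273 ± 6.16 to 0.990 ± 0.408 CPM (-8.10, SE 0.15), and Ddit3, a transcription factor of endoplasmic reticulum stress, rose from 19.3 ± 2.12 to 181 ± 11.5 CPM (3.23, SE 0.10). Of 12807 genes tested, edgeR called 7837, of which 3853 were higher and 3984 lower in the libraries labelled WT 2 h, and 1378 and 1050 of these differed at least 2-fold.

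The 23 tested genes of DNA replication and S phase were all lower in the libraries labelled WT 2 h, as were the 22 genes of mitosis and the 21 of cholesterol synthesis. The counts were the same adjusted over the list alone. Mcm5, a subunit of the replicative helicase, fell from 274 ± 6.90 to 52.9 ± 2.73 CPM (-2.37, SE 0.08). The ribonucleotide reductase subunit Rrm2 fell by 1.73 on the log2 scale (SE 0.08) and the mitotic kinase Plk1 by 1.70 (SE 0.09). Sqle, the squalene epoxidase of sterol synthesis, fell from 343 ± 19.5 to 65.8 ± 1.99 CPM (-2.38, SE 0.08), and Nsdhl and Acat2 fell by 2.54 (SE 0.09) and 2.52 (SE 0.10). The median log2 fold changes were -1.17 for replication (camera adjusted p = 4.16e-13), -1.14 for mitosis (camera adjusted p = 1.85e-13) and -1.71 for cholesterol synthesis (camera adjusted p = 5.75e-15). With an estimated correlation the camera adjusted p was 0.143 for replication, 0.038 for mitosis and 0.0578 for cholesterol synthesis. Of 25 genes of the extracellular matrix 21 were lower and 1 higher, with the same counts adjusted over the list alone. Col3a1 and Fbn1 fell by 3.37 (SE 0.09) and 2.98 (SE 0.08). This list had a median of -1.29 (camera adjusted p = 1.85e-13, and adjusted p = 0.0813 with an estimated correlation).

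Of 15 chemokines and cytokines, 10 were lower and 4 higher in the libraries labelled WT 2 h, with the same counts adjusted over the list alone (median -1.57, camera adjusted p = 0.00852, and adjusted p = 0.259 with an estimated correlation). Ccl2, which attracts monocytes, fell to 6.67 ± 0.558 CPM in the libraries labelled WT 2 h (-3.83, SE 0.11), and Cx3cl1 fell by 3.64 (SE 0.14). Of 29 cytosolic ribosomal proteins 18 were lower and none higher by either adjustment (median -0.41, camera adjusted p = 0.00036, and adjusted p = 0.355 with an estimated correlation). Rpl8 gave -1.29 (SE 0.09) and Rps4x -1.26 (SE 0.09). Of 19 immediate early genes 11 were higher and 4 lower by either adjustment (median 0.56, camera adjusted p = 0.00713, and adjusted p = 0.355 with an estimated correlation). The transcription factor Fosb rose from 4.61 ± 0.328 to 37.5 ± 0.705 CPM and the phosphatase Dusp1 by 2.36 (SE 0.10). Of 18 contractile and TGF-beta responsive genes 11 were higher and 4 lower, and 12 and 4 adjusted over the list alone (median 0.34, camera adjusted p = 0.0226, and adjusted p = 0.355 with an estimated correlation). Ankrd1, a target of the Yap pathway, rose from 138 ± 14.0 to 1045 ± 37.3 CPM, while Id2 fell by 2.08 (SE 0.14).

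The interferon-induced genes were divided between these libraries. Of 14 interferon-inducible GTPases 12 were higher and none lower by either adjustment (median 2.75, camera adjusted p = 0.00036, and adjusted p = 0.355 with an estimated correlation). Gbp9 rose from 2.33 ± 0.598 to 74.6 ± 0.574 CPM and Gbp4 from 0.539 ± 0.00220 to 21.3 ± 0.794 CPM. Of 18 genes of class I antigen presentation 11 were higher and none lower by either adjustment (median 0.42, camera adjusted p = 0.0089, and adjusted p = 0.353 with an estimated correlation). They included B2m (1.40, SE 0.08) and Nlrc5 (2.63, SE 0.22). Of 31 antiviral effectors 11 were higher and 8 lower by either adjustment (camera adjusted p = 0.223), with Ifi44 at -3.22 (SE 0.48). Ifit1 was called at 1.12 (SE 0.32, edgeR adjusted p = 0.00649) but not without the library labelled WT 2 h replicate 2, where its log2 fold change was 0.44. Leaving out each library gave edgeR adjusted p from 4.72e-05 to 0.26. The values of Irf7 (0.04, SE 0.33, edgeR adjusted p = 0.933) and Cxcl10 (-0.19, SE 0.57, edgeR adjusted p = 0.794) did not pass. The guanylate-binding and other family members share sequence, so their single values are uncertain.

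The remaining 16 lists were not called (camera adjusted p 0.185 to 0.829), although single members were. Gadd45a, a target of p53, rose from 5.78 ± 1.27 to 55.5 ± 2.64 CPM, and Tnfaip3, an inhibitor of NF-kB signalling, from 5.92 ± 1.99 to 36.9 ± 4.07 CPM. Nqo1, an enzyme of the oxidative stress response, fell by 1.82 (SE 0.10), and the matrix protease inhibitor Timp1 by 2.04 (SE 0.09). Of markers of other cell types, Vwf, made by endothelium and platelets, rose from 0.416 ± 0.310 to 11.4 ± 1.13 CPM and the muscle filament gene Des from 2.28 ± 0.183 to 16.0 ± 0.218 CPM. The lists of endothelial (1 higher and 1 lower of 5) and skeletal muscle markers (2 higher of 4) were not called. Among genes without reads in a group, Pcdh9, a protocadherin, was at least 102-fold higher and Chi3l1, a secreted chitinase-like protein, at least 90.7-fold lower in the libraries labelled WT 2 h. Scaled by library size alone, the model called 4823 genes higher and 3055 lower, with 6908 calls shared. This moved the median of all genes by 0.14 on the log2 scale. Tested against a fold of 1.5, edgeR called 2939 genes.

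The second comparison asks the same of the cells labelled KO. In the libraries labelled KO 2 h, the tested genes of DNA replication, mitosis and cholesterol synthesis and 21 of 25 matrix genes were lower than in those labelled KO 0 h, and 14 of 19 immediate early genes were higher. Of these 5 list calls, mitosis alone held with an estimated correlation (camera adjusted p = 0.0349, and 0.0639 to 0.25 for the others). Col1a1 fell from 9097 ± 462 to 949 ± 3.33 CPM (n = 2 each, -3.26, SE 0.09), Mcm5 from 263 ± 16.9 to 55.1 ± 1.33 CPM (-2.26, SE 0.08) and Sqle from 316 ± 0.269 to 60.6 ± 0.756 CPM (-2.38, SE 0.08). Ddit3 rose from 21.9 ± 2.01 to 173 ± 8.88 CPM (2.98, SE 0.10) and Fosb from 4.95 ± 0.572 to 35.6 ± 2.16 CPM (2.83, SE 0.14). Among 12807 genes edgeR called 7829, with 3838 higher and 3991 lower in the libraries labelled KO 2 h and 1365 and 1078 of these at least 2-fold.

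By either adjustment, the 23 genes of DNA replication were lower in the libraries labelled KO 2 h (median -1.36, camera adjusted p = 1.68e-13, and adjusted p = 0.132 with an estimated correlation). So were the 22 of mitosis (median -1.28, camera adjusted p = 6.07e-14, and adjusted p = 0.0349 with an estimated correlation). The 21 genes of cholesterol synthesis were lower as well (median -1.59, camera adjusted p = 4.7e-14, and adjusted p = 0.0639 with an estimated correlation). Nsdhl gave -2.82 (SE 0.10) and Acat2 -2.35 (SE 0.10). Of the 25 matrix genes 21 were lower and 2 higher by either adjustment (median -1.26, camera adjusted p = 1.16e-10, and adjusted p = 0.126 with an estimated correlation). Col3a1 gave -3.21 (SE 0.09) and Fbn1 -2.99 (SE 0.08). Of the 15 chemokines and cytokines 10 were lower and 3 higher by either adjustment (median -1.55, camera adjusted p = 0.00385, and adjusted p = 0.203 with an estimated correlation). Ccl2 fell from 174 ± 1.64 to 22.8 ± 2.73 CPM, and Cxcl12, a chemokine of stromal cells, had no reads in the libraries labelled KO 2 h, at least 99.5-fold lower. Of the 29 ribosomal proteins 19 were lower and none higher by either adjustment (median -0.47, camera adjusted p = 0.000717, and adjusted p = 0.344 with an estimated correlation). Rps4x gave -1.32 (SE 0.09).

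Of 19 immediate early genes 14 were higher and 2 lower by either adjustment (median 0.77, camera adjusted p = 3.54e-05, and adjusted p = 0.25 with an estimated correlation). Nr4a1, an orphan nuclear receptor, rose from 57.1 ± 6.06 to 166 ± 4.63 CPM and Dusp1 by 2.58 (SE 0.10). Of 18 contractile genes 10 were higher and 4 lower by either adjustment (median 0.54, camera adjusted p = 0.014, and adjusted p = 0.344 with an estimated correlation). This call was lost without the library labelled KO 2 h replicate 2 (contractile and TGF-beta responsive genes, camera adjusted p = 0.0579). Ankrd1 rose from 152 ± 11.1 to 1106 ± 26.9 CPM. Of 14 GTPases 10 were higher and 1 lower by either adjustment (median 0.68, camera adjusted p = 0.00141, and adjusted p = 0.351 with an estimated correlation). Gbp9 rose from 16.5 ± 1.89 to 163 ± 5.37 CPM. Of 18 antigen presentation genes 12 were higher and none lower, and 12 and 1 adjusted over the list alone (median 0.47, camera adjusted p = 0.00134, and adjusted p = 0.203 with an estimated correlation). B2m gave 1.21 (SE 0.08).

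Of the 31 antiviral effectors 13 were higher and 9 lower, and 14 and 9 adjusted over the list alone, which gave no call (camera adjusted p = 0.154). Oas1a and Oas3, enzymes of the antiviral response, rose by 2.70 (SE 0.22) and 2.46 (SE 0.23), while Ifi44 and Oasl1 fell by 4.06 (SE 0.19) and 3.17 (SE 0.40). Ifit1 rose from 213 ± 23.3 to 388 ± 11.6 CPM (0.87, SE 0.11), and Cxcl10 fell from 25.3 ± 3.29 to 6.37 ± 0.486 CPM (-1.98, SE 0.22). Isg15 did not pass (0.10, SE 0.10, edgeR adjusted p = 0.361). The other 15 lists were not called (camera adjusted p 0.0928 to 0.786). With library size alone 4834 genes were higher and 3036 lower, the median of all genes moved by 0.15, and 6874 calls were shared. Tested against a fold of 1.5, edgeR called 3012 genes.

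Fold changes of the 2 h against 0 h comparisons in the WT and KO labels, which share no library, had a Pearson r of 0.898 and a Spearman rho of 0.880 across 12807 genes, which are not independent replicates. Of the calls, 3152 were higher in both, where independent lists would share 1155. A further 3363 were lower in both (1242 for independent lists), and 11 went in opposite directions. Without the low-count filter the Pearson r was 0.458. Over the 95 genes of the interferon lists, the slope through the origin of the KO change on the WT change was 0.47.

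The third comparison sets libraries labelled KO 0 h against those labelled WT 0 h. By label it is the effect of the knockout without IFN-β, but Zmynd11 did not differ between these groups. If the labels KO 0 h and WT 2 h were exchanged, it would be the response of unedited cells to IFN-β. In the libraries labelled KO 0 h, 70 of the 95 genes of the interferon lists were higher than in those labelled WT 0 h, and none was lower. Mx2, a dynamin-like antiviral GTPase, rose from 0.0977 ± 0.138 to 35.9 ± 2.83 CPM (n = 2 each, log2 fold change 8.42, SE 0.33). Irgm2, a GTPase of cell-autonomous immunity, rose from 0.587 ± 0.275 to 131 ± 10.4 CPM (7.78, SE 0.16), and Usp18, which removes Isg15 from proteins, rose from 0.392 ± 0.0677 to 50.4 ± 0.126 CPM (6.98, SE 0.19). Stat2, a transcription factor of interferon signalling, stood at 14.7 ± 0.00956 CPM in WT 0 h and at 223 ± 9.78 CPM in KO 0 h. Of 12807 genes edgeR called 502, of which 339 were higher and 163 lower in the libraries labelled KO 0 h, and 122 and 1 of these differed at least 2-fold.

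Of 31 antiviral effectors 28 were higher and none lower, and 29 adjusted over the list alone (median 3.08, camera adjusted p = 1.63e-63, and adjusted p = 0.0149 with an estimated correlation). Ifit1 rose by 7.35 on the log2 scale (SE 0.19) and Ifit3 by 5.79 (SE 0.25). Of 21 genes of nucleic acid sensing and interferon signalling 15 were higher and none lower, and 16 adjusted over the list alone (median 1.80, camera adjusted p = 3.88e-41, and adjusted p = 0.0149 with an estimated correlation). They included the RNA sensor Ddx58 (3.11, SE 0.11), Irf9 (3.17, SE 0.12) and Stat2 (3.93, SE 0.10). The 14 GTPases were all higher by either adjustment (median 5.41, and 5.04 with members absent from WT 0 h at their lower bound, camera adjusted p = 3.88e-41, and adjusted p = 0.0351 with an estimated correlation). Igtp rose by 6.93 (SE 0.21) and Iigp1 by 7.42 (SE 0.29), and Tgtp2 was at least 32.9-fold higher. Of 18 antigen presentation genes 10 were higher and none lower, and 13 adjusted over the list alone (median 0.44, camera adjusted p = 1.98e-12, and adjusted p = 0.0351 with an estimated correlation). The proteasome subunit Psmb9 gave 2.49 (SE 0.32).

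Of 15 chemokines and cytokines 6 were higher and none lower, and 9 and 2 adjusted over the list alone (median 0.38, camera adjusted p = 9.15e-06, and adjusted p = 0.0548 with an estimated correlation). Cxcl10, a chemokine for T cells, gave 5.47 (SE 0.31) and Ccl2 0.87 (SE 0.09). Of 11 genes of negative feedback 3 were higher and none lower, and 4 adjusted over the list alone (median 0.20, camera adjusted p = 0.00307, and adjusted p = 0.109 with an estimated correlation). Of 15 NF-kB targets 2 were higher and none lower, and 7 and 1 adjusted over the list alone (median 0.32, camera adjusted p = 0.00307, and adjusted p = 0.273 with an estimated correlation). Of 19 immediate early genes 1 was higher and 2 lower, and 2 and 7 adjusted over the list alone (median -0.22, camera adjusted p = 0.00453, and adjusted p = 0.366 with an estimated correlation). Nr4a1 gave -0.70 (SE 0.09). Of 25 matrix genes 1 was lower, and 2 adjusted over the list alone (median -0.10, camera adjusted p = 0.000703, and adjusted p = 0.273 with an estimated correlation). In the H3.3 and H3K36 methylation list, which was not called (camera adjusted p = 0.0779), Daxx, an H3.3 chaperone that is also interferon-inducible, rose from 24.9 ± 0.344 to 90.1 ± 1.30 CPM.

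A further 4 lists were called by camera, and each call was lost without 1 or more single libraries. Contractile and TGF-beta responsive genes had a median of -0.16 (camera adjusted p = 0.0149, and adjusted p = 0.369 with an estimated correlation), lost without KO 0 h replicate 2 or WT 0 h replicate 2 (camera adjusted p = 0.326 and 0.0643). Cholesterol synthesis had -0.08 (camera adjusted p = 0.022, and adjusted p = 0.366 with an estimated correlation), lost without KO 0 h replicate 2 or WT 0 h replicate 1 (camera adjusted p = 0.153 and 0.0669). Macrophage and leukocyte markers had 0.71 (camera adjusted p = 0.0149, and adjusted p = 0.491 with an estimated correlation), lost without KO 0 h replicate 2 (camera adjusted p = 0.179). Nuclear-retained non-coding RNAs had 0.17 (camera adjusted p = 0.0368, and adjusted p = 0.369 with an estimated correlation), lost without KO 0 h replicate 1 or WT 0 h replicate 1 (camera adjusted p = 0.067 and 0.227). The medians of DNA replication, mitosis and the ribosomal proteins were 0.03, 0.05 and 0.01, and these and the other 10 lists were not called (camera adjusted p 0.0779 to 0.895). Counts and their split by direction depended on single libraries: 533 genes were higher and 540 lower without KO 0 h replicate 1, 257 and 89 without KO 0 h replicate 2, 148 and 26 without WT 0 h replicate 1, and 155 and 36 without WT 0 h replicate 2. With library size alone 275 genes were higher and 221 lower, with RLE factors 306 and 191, and without the low-count filter 424 and 385. Tested against a fold of 1.5, edgeR called 110 genes, each of them higher.

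**Figure D2:**
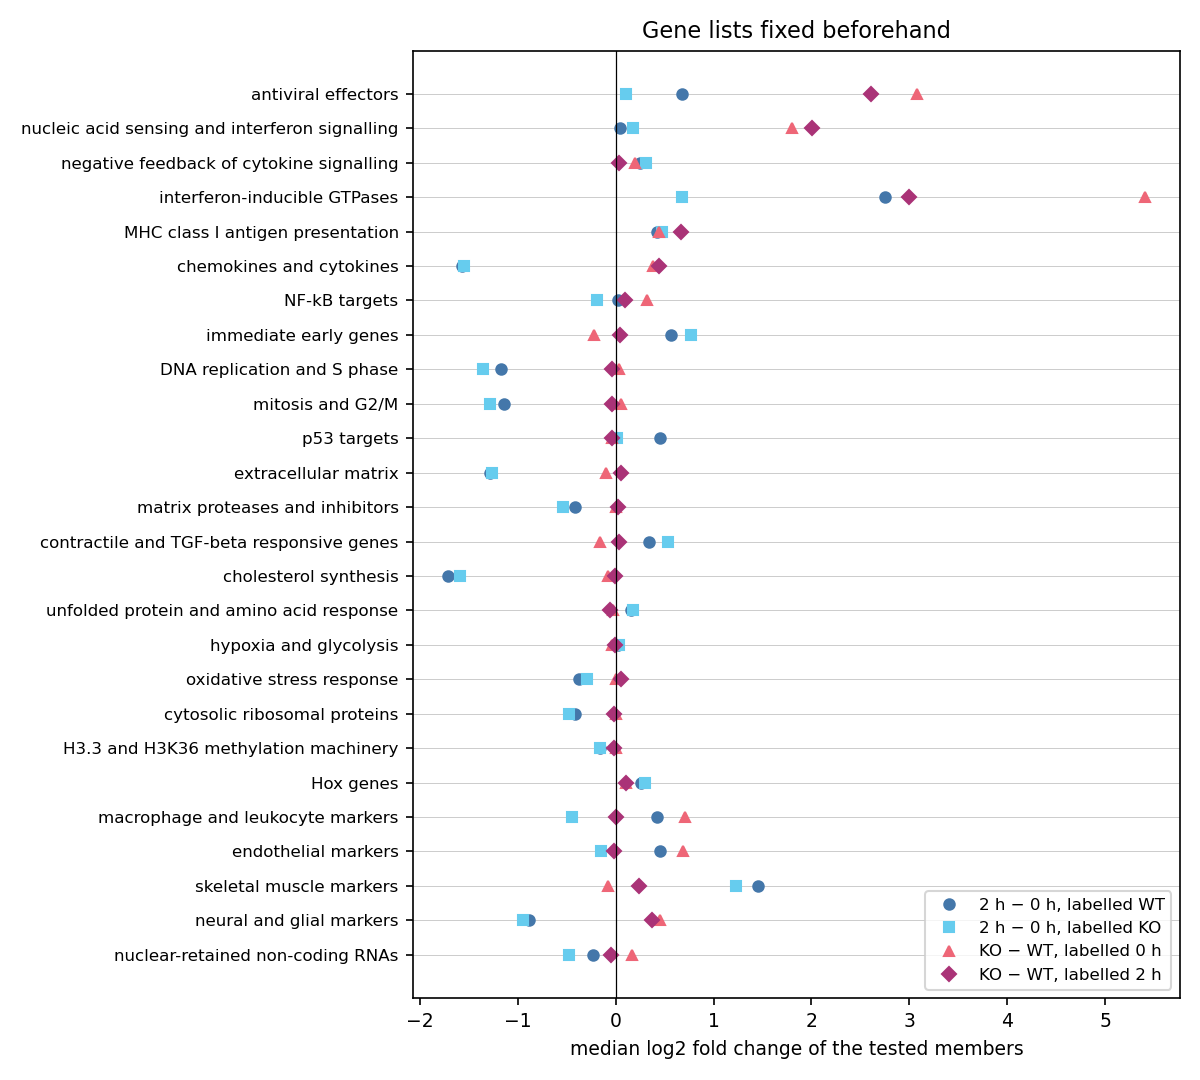
Median log2 fold change of the tested members of each of the 26 gene lists (x axis) in the 4 comparisons between labelled groups, 1 symbol per comparison. Cholesterol synthesis lies at -1.71 and -1.59 between labelled times and near 0 between labelled genotypes, whereas antiviral effectors lie at 3.08 and 2.61 between labelled genotypes.

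The fourth comparison sets libraries labelled KO 2 h against those labelled WT 2 h. By label it is the effect of the knockout under IFN-β, but Zmynd11 was low in both groups. With the labels KO 0 h and WT 2 h exchanged, it would be the response of edited cells to IFN-β. In the libraries labelled KO 2 h, 65 of the 95 genes of the interferon lists were higher than in those labelled WT 2 h, and none was lower. Ifit1 rose from 2.84 ± 1.57 to 388 ± 11.6 CPM (n = 2 each, log2 fold change 7.10, SE 0.17). Irgm2 rose from 4.46 ± 0.255 to 206 ± 4.52 CPM (5.53, SE 0.12) and Usp18 from 3.21 ± 0.260 to 115 ± 12.2 CPM (5.16, SE 0.13). Of 12807 genes edgeR called 205, with 204 higher and 1 lower, and 112 of the higher genes differed at least 2-fold. The lower gene was Zdhhc2, a palmitoyltransferase (-0.85, SE 0.21, edgeR adjusted p = 0.0386), whose call was lost without KO 2 h replicate 1 or without WT 2 h replicate 2 (edgeR adjusted p up to 0.736).

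Of 31 antiviral effectors 26 were higher and none lower, and 29 adjusted over the list alone (median 2.61, camera adjusted p = 3.55e-128, and adjusted p = 0.00395 with an estimated correlation). Of 21 sensing and signalling genes 15 were higher and none lower by either adjustment (median 2.01, camera adjusted p = 8.54e-79, and adjusted p = 0.00395 with an estimated correlation). Stat2 gave 3.57 (SE 0.09), Irf7 3.75 (SE 0.23) and Ddx58 2.75 (SE 0.11). Of 14 GTPases 13 were higher, and 14 adjusted over the list alone (median 2.997, camera adjusted p = 2.55e-84, and adjusted p = 0.009 with an estimated correlation). Igtp gave 4.91 (SE 0.15) and Gbp3 3.93 (SE 0.20). Of 18 antigen presentation genes 8 were higher and none lower, and 12 adjusted over the list alone (median 0.67, camera adjusted p = 1.33e-26, and adjusted p = 0.00869 with an estimated correlation). The peptide transporter Tap1 gave 2.44 (SE 0.12).

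Of 15 chemokines and cytokines 7 were higher and none lower by either adjustment (median 0.44, camera adjusted p = 4.37e-13, and adjusted p = 0.0109 with an estimated correlation). They included Cxcl10 (3.68, SE 0.37), Ccl2 (1.76, SE 0.12) and Il15 (1.69, SE 0.24). Of 11 feedback genes 3 were higher, and 4 adjusted over the list alone (median 0.03, camera adjusted p = 9.22e-05, and adjusted p = 0.0484 with an estimated correlation). Socs1, an inhibitor of Jak kinases, gave 1.89 (SE 0.21). Of 15 NF-kB targets 2 were higher by either adjustment (camera adjusted p = 0.0193, and adjusted p = 0.491 with an estimated correlation), a call lost without KO 2 h replicate 1 or WT 2 h replicate 2 (camera adjusted p = 0.0943 and 0.0559). Of 19 immediate early genes, Zfp36, which destabilises cytokine transcripts, was called (0.76, SE 0.12). The immediate early list had a camera adjusted p = 0.0353, and adjusted p = 0.605 with an estimated correlation. It was lost without KO 2 h replicate 2 or WT 2 h replicate 1 (camera adjusted p = 0.207 and 0.938). Daxx rose from 41.8 ± 1.30 to 168 ± 1.32 CPM (2.01, SE 0.08). The medians of DNA replication, mitosis, cholesterol synthesis and the matrix were -0.04, -0.04, -0.01 and 0.06, and the 18 lists beyond these 8 calls did not pass (camera adjusted p 0.18 to 0.998). Tested against a fold of 1.5, edgeR called 111 genes.

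Fold changes of KO against WT at 0 h and at 2 h, which share no library, had a Pearson r of 0.445 and a Spearman rho of 0.0351 across 12807 genes. Higher in both were 164 genes, where independent lists would share 5.40, and 0 genes were lower in both. Of the 339 genes called higher at 0 h, 265 had the same sign at 2 h. Of the 163 called lower at 0 h, 82 had the same sign at 2 h. Without the low-count filter the Pearson r was 0.0332, and without single libraries it lay between 0.208 and 0.309. Over the 95 genes of the interferon lists the Pearson r was 0.871 and the slope through the origin of the 2 h change on the 0 h change was 0.75.

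**Figure D3:**
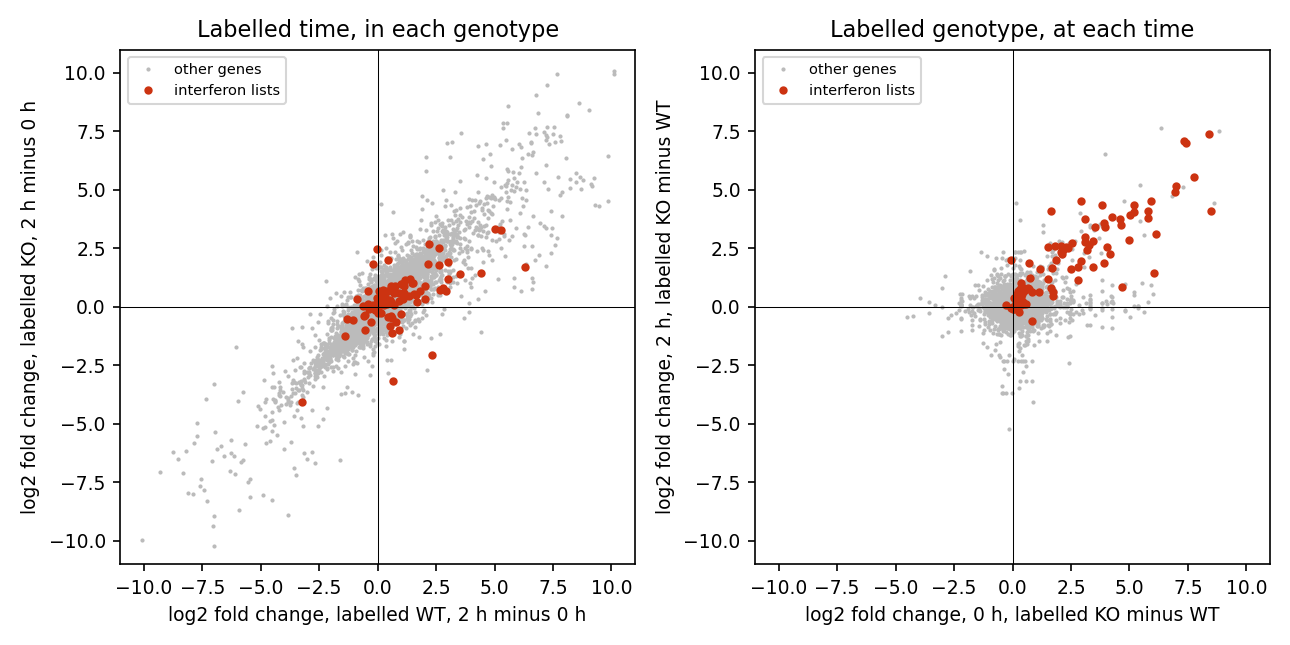
Log2 fold change of each of 12807 genes in 2 comparisons that share no library: labelled 2 h minus 0 h in the KO labels against the WT labels (left), and labelled KO minus WT at 2 h against 0 h (right), with the 95 genes of the interferon lists as larger points. The genes follow the diagonal on the left (Pearson r 0.898), and on the right the 95 genes of the interferon lists have a Pearson r of 0.871.

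The interaction asks whether the 2 h against 0 h change differs between the KO and WT labels, and 6 of its 17 calls were interferon-inducible GTPases. Irgm1 rose from 23.1 CPM to 73.7 CPM between the libraries labelled WT 0 h and WT 2 h and stood at 380 and 439 CPM in those labelled KO 0 h and KO 2 h, which gave an interaction of -1.47 (SE 0.12, edgeR adjusted p = 2.39e-07). Irgm2 gave -2.25 (SE 0.28, edgeR adjusted p = 0.000243), Gbp9 -1.69 (SE 0.19, edgeR adjusted p = 6.15e-05) and Gbp4 -2.01 (SE 0.30, edgeR adjusted p = 0.0024). Of 12807 genes edgeR called 17, with 7 above and 10 below 0. Above 0 was Oas3, with 0.858 ± 0.177 and 0.851 ± 0.211 CPM in the libraries labelled WT 0 h and 2 h against 2.66 ± 0.0170 and 14.8 ± 2.97 CPM in those labelled KO (2.48, SE 0.47, edgeR adjusted p = 0.0216). So were Ccl2 (0.89, SE 0.15, edgeR adjusted p = 0.00936), Ifi204 (0.81, SE 0.13, edgeR adjusted p = 0.00645) and Nr4a1 (0.76, SE 0.13, edgeR adjusted p = 0.00855), beside Snai1, Slc25a22 and Agrn.

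Of 14 GTPases 6 had a negative interaction and none a positive one, and 11 adjusted over the list alone (median -1.997, camera adjusted p = 3.1e-15, and adjusted p = 0.563 with an estimated correlation). Of 19 immediate early genes 1 was positive, and 5 adjusted over the list alone (median 0.24, camera adjusted p = 6.35e-05, and adjusted p = 0.563 with an estimated correlation). Of 25 matrix genes 1 was positive adjusted over the list alone (median 0.15, camera adjusted p = 7.43e-05, and adjusted p = 0.563 with an estimated correlation). Macrophage and leukocyte markers had a median of -0.70 (camera adjusted p = 0.00738, and adjusted p = 0.805 with an estimated correlation), lost without KO 0 h replicate 2 or KO 2 h replicate 1 (camera adjusted p = 0.0796 and 0.815). Nuclear-retained non-coding RNAs had -0.25 (camera adjusted p = 0.0222, and adjusted p = 0.706 with an estimated correlation). That call was lost without KO 0 h replicate 1, KO 2 h replicate 2, WT 0 h replicate 1 or WT 2 h replicate 1 (camera adjusted p 0.0566 to 0.222). The other 21 lists were not called (camera adjusted p 0.0825 to 0.96), among them the antiviral effectors with 1 positive and 1 negative gene, and 5 and 10 adjusted over the list alone. Isg15 (0.54, SE 0.20, edgeR adjusted p = 0.296) and Ifit1 (-0.25, SE 0.34, edgeR adjusted p = 0.808) did not pass. Leaving out single libraries gave 6 to 91 calls: 91 without KO 0 h replicate 1, 30 without KO 0 h replicate 2, 35 without KO 2 h replicate 2, 9 without WT 0 h replicate 2 and 6 without WT 2 h replicate 1. Irgm1, Irgm2, Gbp9 and Gbp4 were called without each of the 8 libraries, the other 13 genes were not, and DESeq2 called 32 genes, of which 14 were shared. DESeq2 gave no adjusted p to 12512 genes, so its count rests on another set of genes than that of edgeR. Without the low-count filter 113 genes were called, 56 above and 57 below 0.

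**Figure D4:**
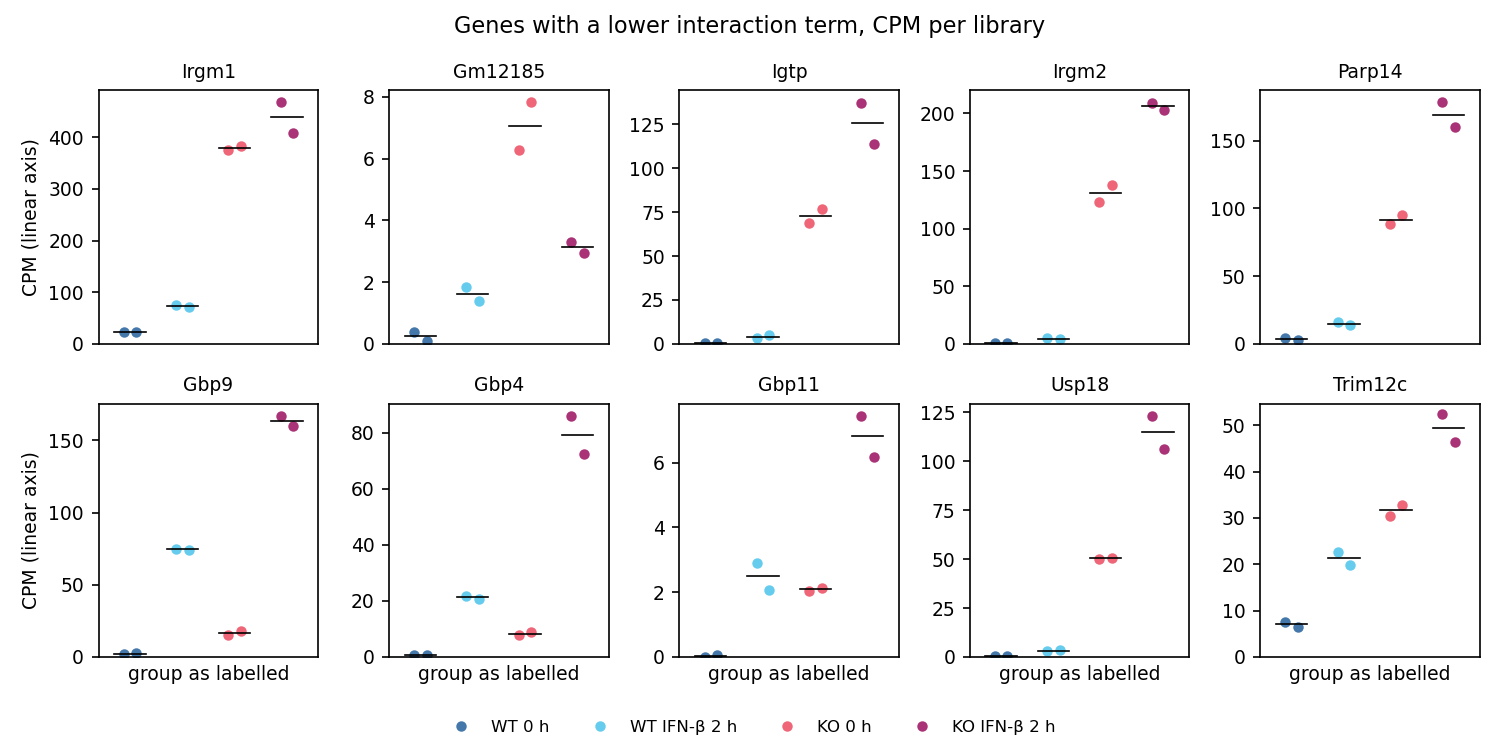
CPM on linear axes of the 10 genes with a negative interaction, for each library by labelled group, with points for libraries and lines for group means. Irgm1 lies at 23.1 and 73.7 CPM in the groups labelled WT and at 380 and 439 CPM in those labelled KO, and Gm12185 alone has a lower mean in KO 2 h (3.13 CPM) than in KO 0 h (7.06 CPM).

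Markers of other cell types were summarised by the median of each list, which hides single members above it, among them Des and Vwf in the libraries labelled 2 h. Over 10 epithelial markers the median stood between 0 and 0.110 CPM in the 8 libraries and over 8 adipocyte markers between 0.0566 and 0.480 CPM, and these lists were not tested because fewer than 3 members passed the filter. The medians were 0.117 to 0.607 CPM for endothelial, 0.180 to 0.530 CPM for skeletal muscle, 0.0722 to 0.512 CPM for neural and 2.42 to 5.31 CPM for macrophage markers. Transcripts of the mitochondrial genome were not analysed here, since none of the 10 listed genes is among the gene symbols of the tables.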

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

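The tests of a ceiling, of the scaling and of Irgm1 and Trim12c alone in this part were chosen only after the results were seen, while the test of added amounts over the 10 genes was written before.

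The change between libraries labelled 2 h and 0 h differed between the KO and WT labels in 17 genes, each by the interaction term of the edgeR model. Above 0 on the log2 scale were Oas3 (2.48), Ccl2 (0.89), Ifi204 (0.81), Snai1 (0.77), Nr4a1 (0.76), Slc25a22 (0.72) and Agrn (0.58). Below 0 were Trim12c (-0.96), Parp14 (-1.13), Irgm1 (-1.47), Gbp9 (-1.69), Usp18 (-1.82), Gbp4 (-2.01), Igtp (-2.02), Irgm2 (-2.25), Gm12185 (-3.85) and Gbp11 (-4.61). Gbp11 had 1 read in the libraries labelled WT 0 h and 91 in those labelled WT 2 h, a ratio of 102 with a 95% counting interval of 17.8 to 4060. Irgm1, Irgm2, Gbp9 and Gbp4 were called without each of the 8 libraries, and the other 13 genes lost their call without 1 or more of them. Without WT 2 h replicate 1 alone, 6 genes were called.

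The 10 genes below 0 were all called higher in the libraries labelled WT 2 h than in WT 0 h (median log2 fold change 2.86). A common ceiling already reached in KO 0 h would leave no rise in the libraries labelled KO 2 h. The median there was 0.84, and the SE of the mean over the genes was 0.43. Of the 10 genes 9 were called higher, which argues against a full ceiling for these 9. The genes were picked by their interaction and are not replicates, and a partial ceiling, which only lessens the rise, is not excluded. Scaling of the libraries would shift the interaction of all genes alike. Its median over all genes was -0.0079 as fitted and 0.0021 with library size alone, against a weighted mean of -1.54 in the 10 genes. All 10 were also called with RLE factors and with library size alone, and 5 of the 10 lay more than 2 standard errors from their weighted mean. These values argue against scaling as the only source. Amounts that add rather than multiply would give equal differences in CPM, but in 8 of the 10 genes these differed by more than 2 standard errors, in 7 of them upward in CPM although the log2 interaction is negative, and downward in Gm12185. For Irgm1 and Trim12c, 2 of 2 genes lay within 2 standard errors. They were singled out as the genes of the 10 not beyond that limit, so the choice fixed the outcome, and added amounts stay open for them. For the others the interaction term is itself the test of a difference in the response between genotypes. The groups KO 0 h and WT 2 h enter that term with the same sign, so an exchange of these 2 labels would not change it. The cause of that difference was not tested.

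The library labelled KO 0 h replicate 2 held reads of 1192 genes that had no read in any other library, against 78 to 178 such genes in the others. These came to 2642 reads, and at most 16 were of 1 gene.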

How the results depend on the processing

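The fits without the library labelled KO 0 h replicate 2 for the comparisons that do not contain it were chosen after the data were seen, and the other alternatives before. No called value of a named gene or list reversed its direction. Values of Zmynd11 that were not called changed sign: KO against WT at 2 h went from 0.19 to -0.05 without KO 2 h replicate 2, and the interaction from 0.05 to -0.05 without WT 2 h replicate 1 and to -0.19 without KO 2 h replicate 2. Tested against a fold of 1.5, the calls were 2939 for 2 h against 0 h in WT, 3012 in KO, 110 for KO against WT at 0 h, 111 at 2 h and 5 for the interaction, fewer because small changes are excluded by construction. Without the low-count filter, KO against WT at 0 h gave 809 calls and the interaction 113, and Pearson r fell to 0.458 between the labelled times and 0.0332 between the labelled genotypes, since genes with few reads enter. DESeq2 called 32 interaction genes but gave no adjusted p to 12512 genes, so its count rests on another set of genes, and how far this matters was not tested. The replicate block gave 322 calls for KO against WT at 0 h, 245 higher and 77 lower, and moved no other count by over 1.5 times. Replicate numbers did not pair the samples (correlations of deviations -0.0533 to -0.00530). Leaving out each library gave 6425 to 6726 calls in WT, 6850 to 7379 in KO, 174 to 1073 for KO against WT at 0 h, 147 to 189 at 2 h and 6 to 91 for the interaction. Pearson r then lay between 0.781 and 0.862 for the labelled times and between 0.208 and 0.309 for the labelled genotypes. In these fits the low-count filter was run again with a group of 1 library, which lets in more genes with few reads. The genes tested therefore changed along with the libraries, and the share of each in the shift was not tested. With an estimated correlation camera called 1 list in WT, 1 in KO, 4 for KO against WT at 0 h, 6 at 2 h and 0 for the interaction, against 10, 10, 13, 8 and 5, and the cause was not tested. Over the alternatives, values of named genes lost their call 202 times and gained one 18 times, and those of the interaction genes 48 and 7 times. These totals include the test against a fold of 1.5. That test lost 13 named calls in WT, 15 in KO, 24 for KO against WT at 0 h and 7 at 2 h, and left 5 interaction calls. Without the doubted library the calls were 8201 in WT and 220 for KO against WT at 2 h. Counting on the other strand was not run, since the tables hold 1 column of counts. Depth limits genes near 0.138 to 0.210 CPM, the level of 3 reads.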

Other observations

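The tests of the labels and of the scaling in this part were chosen only after the results were seen, as were the genes and chromosomes named, while the tests of whole chromosomes and of neighbouring genes were written before.

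A few genes that were neighbours among the tested genes of chromosome X were lower in the libraries labelled 2 h, and Msl3 and Hccs were nearly absent there. Msl3, a subunit of a histone acetyltransferase complex, had 2686 reads in the libraries labelled WT 0 h and 12 in WT 2 h, and 2490 and 13 in the KO labels. Hccs, which attaches haem to cytochrome c, had 1776 and 9 reads in the WT labels and 1527 and 7 in the KO labels, and Mid1, a ubiquitin ligase, had 923 and 90, and 778 and 59. Prps2, next to Msl3 among the tested genes in the order of the GRCm38.p6 assembly, gave -0.46 (SE 0.09) and -0.54 (SE 0.10). Genes that were not tested can lie between them. Over the 415 tested genes of chromosome X the median of the log2 fold change between labelled 2 h and 0 h, averaged over the WT and KO labels, was -0.71, against -0.12 to 0.17 in 10000 random lists. In all, 8 of 20 chromosomes had a median beyond each of their own 10000 random lists. It was -0.58 over 504 genes of chromosome 15, 0.64 over 362 genes of chromosome 18, and -0.26, -0.20, -0.13, 0.21 and -0.23 on chromosomes 1, 3, 8, 10 and 12. Between labelled genotypes the largest chromosome median was 0.10 at 0 h and 0.02 at 2 h in size.

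Zmynd11 and Ifit1 go against the labels of 2 groups. All 4 libraries labelled KO 0 h and WT 2 h lay on the other side of the midpoints of 20.9 CPM for Zmynd11 and 22.01 CPM for Ifit1, and 0 of the other 4 did. A single wrong label would put 1 library out of place, and 4 were. Labels that are right, with a response to 2 h of interferon, would leave every chromosome near 0, but chromosome X had a median of -0.71. An exchange of the labels KO 0 h and WT 2 h would put 4 of these 4 libraries out of place, but that count restates the values that raised it and cannot test it. The chromosome medians did not raise it. Between labelled times they were -0.67 and -0.79 (WT and KO labels) on chromosome X, -0.62 and -0.55 on 15, and 0.69 and 0.60 on 18. Between labelled genotypes the largest was 0.10 at 0 h and 0.02 at 2 h in size. An exchange would give this if edited and unedited cells differed on these chromosomes, which was not tested. Between labelled KO 0 h and WT 0 h, 70 of the 95 genes of the interferon lists were higher and none lower, while Zmynd11 did not differ. Different cells under each time label would not by itself account for that difference, whereas an exchange would account for it and for Zmynd11.

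Genes that differ between labelled 2 h and 0 h numbered 7837 in the WT labels. Shifts of whole chromosomes could be a source, but 6615 genes (84.4%) were still called in the same direction after each chromosome's median was removed. After removal of the median of 20 neighbouring genes 6280 (80.1%) were, and the lowest number shared with another scaling of the libraries was 6874 (87.8%), in the KO labels. If the labels were exchanged, these comparisons would set Zmynd11-edited cells against unedited cells, and loss of Zmynd11 and other differences between the cell lines would both stay open and untested.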
